A study of Mus musculus with 12 samples.

How the data were processed

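RNA was sequenced from c-Kit(+) cells of mouse hearts and from 1 preparation of cardiomyocytes. Per the labels' protocols, 8-week C57BL/6 mice with an inducible Cre at the c-Kit locus received 0.5 mg of tamoxifen a day for 14 days, which marked c-Kit(+) cells with eGFP, and then had a myocardial infarction (MI). Vehicle or Sfrp2, a secreted protein that binds Wnt ligands, was given 2 days after MI. The 12 libraries comprise pre-MI (n = 3), day 1 post-MI (n = 2), day 12 vehicle (n = 3), day 12 Sfrp2 (n = 3) and cardiomyocytes of sham mice (n = 1). The day 1 libraries carry the word vehicle in their labels although the stated treatment day comes later. Column names in the deposited tables give day 14 where the labels and sheet names give day 12, and the labels were followed. The labels do not say which libraries came from separate animals, so p-values measure the spread between these libraries, which may be partly technical. Reads of X-linked and Y-linked genes, given below, show that the day 12 Sfrp2 libraries do not all come from the same animals.

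Per the labels' protocols, the RNA was amplified as cDNA with a whole-transcriptome kit, reads were trimmed with Trim Galore and Cutadapt and kept from 20 nt, aligned with STAR to GRCm38, kept where they mapped to 1 place, and counted per gene with HTSeq. Genes with at least 10 reads in any library were kept and DESeq2 was used for normalization and testing. Tool versions are not given in the sources used here. The authors deposited 10 tables of 15223 genes, 13920 of them coding. Each table holds normalized values per library, a signal in units of gene counts divided by a size factor, per the file headers and values. The deposited tables also hold the authors' log2 fold change, a test statistic (a score) and p-values, raw and adjusted. A library's values were identical in every table that held it.

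Each library's values were whole multiples of 1 step, and dividing by it gave whole reads for 100% of values within a tolerance of 0.001. Total recovered reads ranged from 190259 to 3570993 per library. These totals cover the listed genes only. Reads without molecular identifiers are not independent molecules, so read counts state counting error only. Because the tables hold normalized values, the main test was limma with a trended variance on log2(value + 1), fitted to the libraries of the 2 groups compared, with Benjamini-Hochberg adjustment over 15223 genes and a threshold of 0.05. A log2 difference on this scale understates the change of genes with low values. The fixed gene lists (26) were tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation and fry beside it. The sarcomere score, the mean log2(value + 1) over the sarcomere list, was compared by an exact 2-sided permutation test, which cannot go below p = 0.1 for 3 against 3 libraries. The cardiomyocyte library has no replicate and was described by each list's percentile among 10000 random lists matched on mean expression. Groups, tests, lists, the naming rule and the first group of alternatives below were set before the data were examined.

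The naming rule took up to 10 rises and 10 falls per comparison, by size of the log2 difference, among genes past the threshold with a mean of at least 50 in the higher group, no overlap between the groups' libraries and a symbol that is not a predicted gene. Where fewer than 5 genes passed, the 10 with the smallest p were taken and are stated as not passing. Up to 4 members of each list with the smallest p could be named, and Kit, Sfrp2, Axin2, Myh6, Tnnt2, Actc1 and Gata4 in every comparison (Nkx2-5 is not among the listed genes).

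Classes of genes that describe background were chosen after the values were seen. The first holds 97 olfactory, vomeronasal and taste receptor genes, called sensory receptor genes here, of which 94 had an exon length. The second holds 7 predicted genes on chromosomes 2, 9 and 14 with very high reads, called satellite-like genes here. Exon lengths and coordinates came from a GENCODE annotation of GRCm38, which matched 15061 of the listed genes (98.94%). A gene was called above background where its value per exon kb exceeded the 95th percentile of the sensory receptor genes in every library of its higher group. That level was 0 in the 3 pre-MI libraries, so the measure is used for rises after MI only. Genes with background reads alone can exceed it, so a count above background is not a count of genes with RNA.

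The fits were tested on simulated data, 10 draws per comparison over 15223 genes, with the real means, size factors and dispersions. In each draw 200 genes were changed 4-fold or 16-fold, and 1 list of 20 further genes was changed 4-fold. All were drawn from genes with a mean of at least 20, so recovery at lower means was not measured. An unchanged gene had the same mean in both groups, so differences in background between libraries were not simulated. The changed list was found in 10 of 10 draws of each comparison and 0 of 250 unchanged lists were called. Genes were drawn independently of each other, so these list counts do not test camera's preset where members of a list are correlated. For day 1 post-MI against pre-MI the main test recovered 22.7% of genes changed 4-fold and 72.1% of those changed 16-fold. In that comparison 1076 of its 2077 calls (51.8%) were unchanged genes, 1072 of which had a mean under 10. With genes of a mean of at least 10 only, 59 of 2135 calls were unchanged genes. For day 12 Sfrp2 against pre-MI the main test recovered 78.2% and 99.7% at the same folds and 0.914% of its calls were unchanged genes. For day 12 vehicle against pre-MI it recovered 0% and 10.5%, and for day 12 Sfrp2 against day 12 vehicle 4.1% and 65.2%. For day 1 post-MI against day 12 vehicle it recovered 0% and 2.3%, and against day 12 Sfrp2 73.3% and 99.2%. On the same draws edgeR recovered 82.8% and 99.6% for day 1 post-MI against pre-MI, with 2.23% of its calls unchanged genes, and 9.2% and 79.0% for day 12 vehicle against pre-MI, with 5.61%. It recovered 93.3% and 100% for day 12 Sfrp2 against pre-MI and 1.3% and 49.6% for day 12 Sfrp2 against day 12 vehicle, with 3.67% and 4.31% of calls unchanged. For day 1 post-MI it recovered 0.6% and 18.7% against day 12 vehicle and 77.6% and 99.8% against day 12 Sfrp2, with 8.06% and 4.33%.

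Alternatives were pseudocounts of 0.1 and 8, genes with a mean of at least 10, TMM scaling, all 11 c-Kit libraries in 1 fit, the replicate number as a block, each library left out, the authors' deposited adjusted p-values, DESeq2 on the recovered reads and a threshold of 0.1. Added after seeing the data were edgeR's quasi-likelihood test on the recovered reads, a weight per library, centring of the median log2 difference, subtraction of the sensory receptor level per exon kb, and list tests among genes with a mean of at least 50. edgeR called 2635, 1907, 8478, 0, 0 and 121 genes in the 6 comparisons in the order reported. Versions were R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.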

Results

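RNA of c-Kit(+) heart cells was sequenced before MI, 1 day after MI, and 12 days after MI in mice given vehicle or Sfrp2, with 1 library of cardiomyocytes from sham mice. The 3 pre-MI libraries held 3462396 to 3570993 recovered reads, the 2 day 1 libraries 1793826 and 2085161, the day 12 Sfrp2 libraries 1159703 to 2683841 and the day 12 vehicle libraries 200641 to 2349774. The cardiomyocyte library held 190259. Both mitochondrial rRNA genes together took 82.6% to 86.7% of the reads in pre-MI libraries but 2.01% in day 12 vehicle replicate 3 and 1.08% in the cardiomyocyte library. Outside mitochondrial and satellite-like genes, 97041 to 375082 reads remained per library.

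Libraries also differed in reads of sensory receptor and satellite-like genes. Sensory receptor genes held 0 to 6 reads in each pre-MI library. They held 141 and 298 reads in the day 1 libraries, 253 to 725 in the day 12 Sfrp2 libraries and 67 to 663 in the day 12 vehicle libraries. Satellite-like genes took at most 0.232% of pre-MI reads, 3.57% to 19.0% in day 12 Sfrp2 libraries, and 15.7%, 1.13% and 39.3% in day 12 vehicle replicates 1, 2 and 3. Genes at 0 made up 33.9% to 42.1% of pre-MI libraries and 0.19% to 1.66% of day 12 Sfrp2 libraries.

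**Figure D1:**
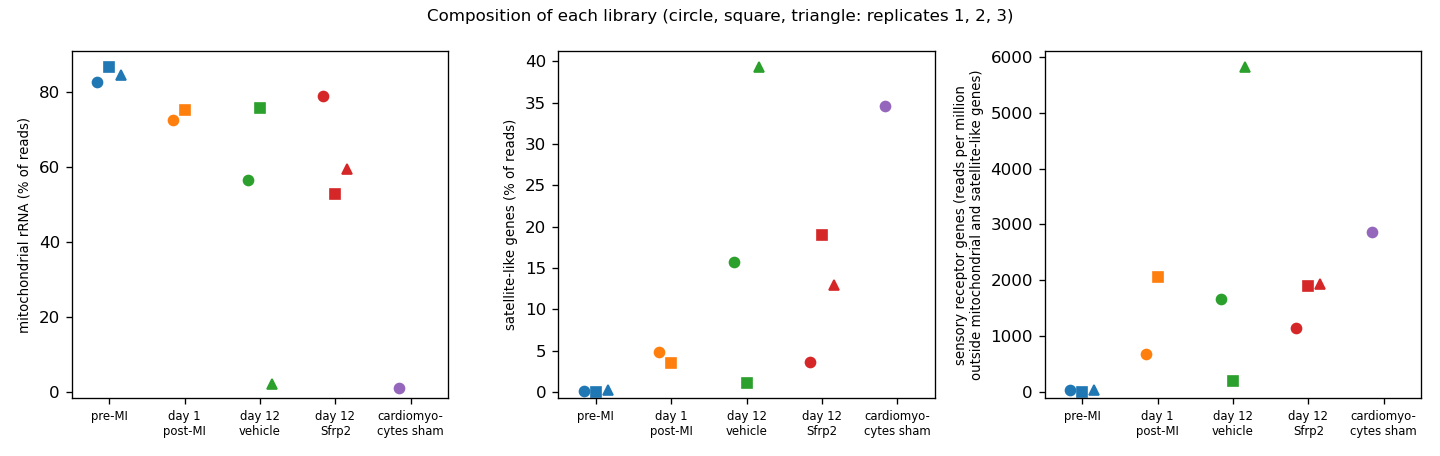
Share of reads in mitochondrial rRNA genes (left, percent), in satellite-like genes (middle, percent) and reads of sensory receptor genes relative to reads outside mitochondrial and satellite-like genes (right, scaled as on the axis), by group; each point is 1 library. Day 12 vehicle replicate 3 and the cardiomyocyte library stand highest in satellite-like reads, at 39.3% and 34.6%.

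The first comparison asked how c-Kit(+) cells differed 1 day after MI from cells before MI. The chemokine genes Ccl9 (106 ± 7.28, SD, n = 2) and Ccl6 (66.5 ± 6.36) and the matricellular gene Spp1 (73.8 ± 20.0) had 0 reads in all 3 pre-MI libraries. Their means were at least 19.7-fold, 12.4-fold and 13.7-fold above the value of 3 reads in the shallowest pre-MI library. The complement gene C3 was at 242 ± 73.7 (n = 2) against 5.58 ± 0.173 (n = 3), a log2 difference of 5.17 (SE 0.253, limma adjusted p = 0.00572). Itgam, an integrin of myeloid cells, rose by 5.64 (SE 0.626) and the complement receptor gene C5ar1 by 5.41 (SE 0.952). Cxcl2, S100a4, Pid1 and Cd44 rose by 5.73, 5.60, 5.13 and 4.06 on the log2 scale.

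Among fixed lists at day 1, 10 of 16 macrophage and monocyte genes and 10 of 14 inflammatory cytokine genes rose, and none fell. Adjusted over the list alone, 12 and 10 passed. Il1b was at 29.8 ± 16.1 and Ccr2, a chemokine receptor of monocytes, at 38.7 ± 12.6 (n = 2), both with 0 in pre-MI; Ccr2 did not lie above background. In the epicardial and mesothelial list 6 of 8 genes rose, among them Upk1b (26.7 ± 20.7 against 0), Msln (16.6 ± 7.44 against 0.379 ± 0.656) and Aldh1a2 (16.7 ± 8.82 against 0). The camera adjusted p was 0.00221 for the macrophage and inflammatory lists and 0.0171 for the mesothelial list; with an estimated correlation the adjusted p was 0.372, 0.372 and 0.485.

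Sarcomere genes fell in 13 of 22 members at day 1 and rose in none, with a median 2.38 below that of all genes on the log2 scale; 16 passed adjusted over the list alone. Actc1, cardiac actin, fell by 2.93 (SE 0.143), from 669 ± 60.4 to 86.5 ± 5.44. Tnnt2, cardiac troponin T, fell by 2.90 (SE 0.405) and Myh6, the main myosin heavy chain of the adult mouse heart, by 2.89 (SE 0.330). In the endothelial list 11 of 18 genes fell, with Cdh5 from 445 ± 45.6 to 125 ± 27.4 and Fabp4 from 1970 ± 86.2 to 628 ± 199; 13 passed adjusted over the list alone. The oxidative phosphorylation list, which also holds ATP synthase genes, is called the respiratory chain list here. In it 11 of 45 members fell, among them the ATP synthase gene Atp5a1 by 1.75, and 14 passed adjusted over the list alone. The camera adjusted p was 2.34e-15, 2.03e-14 and 6.75e-20 for these lists, and the adjusted p was 0.372 for each with an estimated correlation. Among genes with a mean of at least 50 the camera adjusted p was 0.0191 for the sarcomere, 0.0431 for the endothelial and 0.121 for the respiratory chain list, with 10, 12 and 3 members. These members had median log2 differences of -2.32, -1.62 and -1.65, against -0.737 for all genes at that level. Other large falls were Igf2 (3.38), the basement membrane collagens Col4a1 (3.21) and Col4a2 (2.87), Aplnr (3.14), Pln (2.95), Stk16 (2.77) and Sgk1 (2.58).

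Over all genes at day 1, 3235 were higher and 403 lower by limma, with a median log2 difference of 0.702 over 15223 genes. Among genes with a mean of at least 10 the split was 159 higher and 433 lower, and after centring of the median it was 1518 and 1377. In simulation, with 200 genes and a list of 20 changed, 51.8% of calls without that filter were unchanged genes, nearly all at means under 10. They numbered 90 to 126 per draw. The share depends on how many genes were changed, so it does not carry over to the 3638 calls here. Of the 3235 higher genes 194 lay above background. A fit of all 11 c-Kit libraries called 895 genes, DESeq2 942 and edgeR 2635, and the authors' deposited p-values gave 312.

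At day 12 with vehicle, no gene passed against pre-MI (smallest limma adjusted p 0.0661; 5150 genes at an unadjusted p under 0.05 where 761 are expected by chance). DESeq2 called 1075 genes, edgeR 1907, and the authors' deposited p-values gave 3916. Of the genes with the smallest p, none passing, Myh6 was at 24.8 ± 12.1 against 331 ± 106 (n = 3 each) and Itgam at 79.8 ± 66.7 against 0.631 ± 1.09. Of the genes named here that were higher with vehicle, Csf2ra alone lay above background. Pid1 was at 87.2 ± 60.1 against 2.21 ± 1.25 and Csf2ra at 54.0 ± 47.6 against 0.379 ± 0.656. Olr1, Dock2 and Sh3rf3 were at 29.8, 22.8 and 28.2 with 0 reads in pre-MI, and Srrm4 and St6galnac5 at 29.9 and 51.6 against 0.694 and 1.33. The mitochondrial tRNA gene mt-Te was at 62.4 ± 34.2 against 720 ± 145.

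The 3 vehicle libraries differed from each other. C3 was at 74.0, 596 and 9.35, Lyz2 at 52.2, 787 and 1.87, and Actc1 at 45.9, 142 and 5.61 in replicates 1, 2 and 3. Without replicate 2, the vehicle library with the fewest sensory receptor reads, limma called 6421 genes; without any other single library of this comparison, replicate 3 included, it called 0. A weight per library gave 8282. By camera the sarcomere (median log2 difference -2.66), endothelial (-2.22) and respiratory chain (-2.17) lists were lower, against 1.00 for all genes, with adjusted p of 1.92e-18, 1.08e-17 and 1.19e-27. With an estimated correlation the adjusted p was 0.255, 0.256 and 0.255. Among genes with a mean of at least 50 the camera adjusted p was 0.0225 for the sarcomere, 0.0453 for the endothelial and 0.359 for the respiratory chain list, with 8, 11 and 3 members. These members had median log2 differences of -3.42, -2.43 and -3.87, against -1.65 for all genes at that level. The macrophage and monocyte list (median 2.33) and the canonical Wnt target list (2.13) were higher by camera, with adjusted p of 0.000291 and 0.0262, and the adjusted p was 0.324 for both with an estimated correlation. Adjusted over the list alone 11 of 16 and 9 of 13 members passed, and over all genes none did. In replicates 1, 2 and 3 the mean log2(value + 1) was 3.301, 4.982 and 2.819 over the macrophage list. Over the Wnt target list it was 3.467, 2.504 and 3.253, and 3.647 in the cardiomyocyte library. Satellite-like genes took 15.7%, 1.13% and 39.3% of reads in these replicates.

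**Figure D2:**
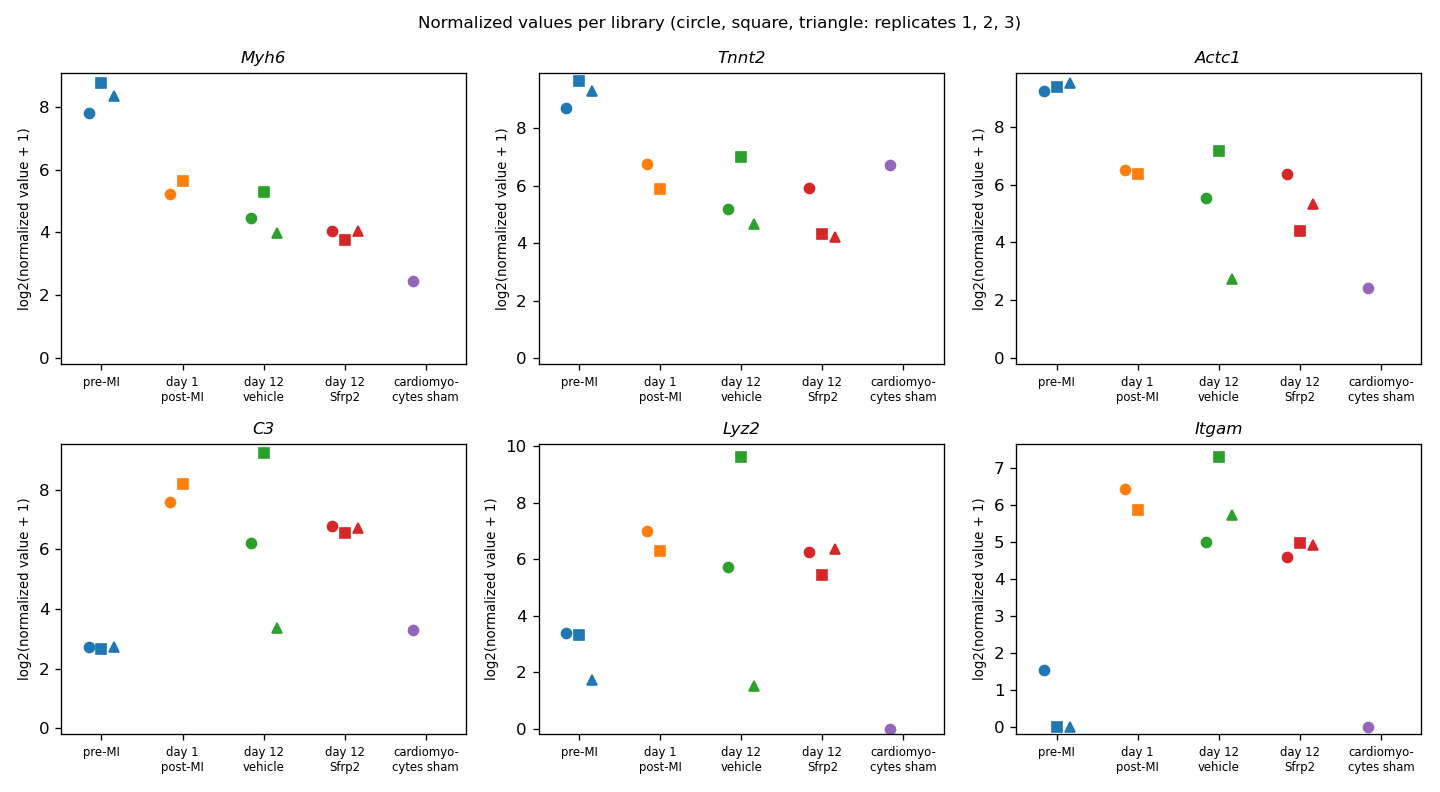
Normalized values of 3 sarcomere genes (top) and 3 immune genes (bottom) on a log2(value + 1) scale, by group; each point is 1 library. All 8 c-Kit(+) libraries after MI lie below the 3 pre-MI libraries for Myh6, and day 12 vehicle replicates 2 and 3 hold C3 at 596 and 9.35.

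At day 12 with Sfrp2, sarcomere and endothelial genes were far below pre-MI. Tnnt2 fell by 4.40 (SE 0.486), from 615 ± 195 to 32.1 ± 24.1 (n = 3 each, limma adjusted p = 0.00037). Myh6 fell by 4.37 (SE 0.302), from 331 ± 106 to 14.5 ± 1.71, and Actc1 by 4.01 (SE 0.458). Tpm1, Myl3 and Tnni3 fell by 3.53, 3.52 and 3.49. In the sarcomere list 18 of 22 genes fell and 1, Myh7, rose; in the endothelial list 17 of 18 fell and 1, Vwf, rose, neither of the rises above background. In the respiratory chain list 34 of 45 members fell. Adjusted over the list alone 19, 18 and 37 passed. Mb, myoglobin, fell by 3.47, Slc25a4, a mitochondrial ADP/ATP carrier, by 3.49, Slc26a10 by 3.56 and mt-Te by 3.53. Camera gave adjusted p of 2.96e-15, 1.76e-16 and 2.55e-24 for the 3 lists, and the adjusted p was 0.172 for each with an estimated correlation. With genes of a mean of at least 50 only, the camera adjusted p was 0.171 for the sarcomere and the endothelial list and 0.763 for the respiratory chain list, with 8, 11 and 3 members. These members had median log2 differences of -3.53, -2.70 and -2.47, against -1.83 for all genes at that level. The fibroblast and matrix list, not called over all genes (0.768; adjusted p 0.855 with an estimated correlation), was higher there (0.0349, 3 members).

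Among rises at day 12 with Sfrp2, C3 (102 ± 8.21 against 5.58 ± 0.173), the macrophage lysozyme gene Lyz2 (66.0 ± 20.9 against 6.90 ± 4.02) and the collagen gene Col1a2 (59.9 ± 6.93 against 15.9 ± 5.94) lay above background. So did Sfi1 (487 ± 122 against 16.6 ± 11.5) and the neighbours Mroh2a (75.7 ± 23.3) and Hjurp (67.6 ± 8.82) on chromosome 1, at 88226986 to 88262289 and 88262471 to 88277633. Sfi1 lies on chromosome 11 at 3131850 to 3193463. Sfi1 was at 682, 91.3 and 711 and Mroh2a at 98.1, 11 and 245 in day 12 vehicle replicates 1, 2 and 3, where satellite-like genes took 15.7%, 1.13% and 39.3% of reads. In the cardiomyocyte library, with 34.6%, they were at 2323 and 148. The long genes Ank3, Celf2, Satb1 and Ank2 rose by 4.12, 2.95, 2.31 and 1.48 without lying above background. Col1a2 and Hjurp rose by 1.90 and 1.55, where the median over all genes was 1.27. Among 18 alternatives Col1a2 and Hjurp lost the threshold in 1 each, Ank2 in 3 and Satb1 in 8. Satb1 was at 177 in Sfrp2 replicate 1 and 17.6 in each of the others. Macrophage and monocyte genes rose in 13 of 16 members and inflammatory genes in 12 of 14 (camera adjusted p 0.00899 and 0.0494; adjusted p 0.172 for both with an estimated correlation). Adjusted over the list alone 15 and 12 passed. Canonical Wnt target genes rose in 12 of 13 members and 1, Ccnd1, fell (13 adjusted over the list alone). The camera adjusted p was 0.0579. Of all 15223 genes 7426 were called higher. The mean log2(value + 1) over the Wnt target list was 3.345 to 3.515 in the Sfrp2 libraries and 0.997 to 1.134 pre-MI. It was 3.467, 2.504 and 3.253 in vehicle replicates 1, 2 and 3, and 3.647 in the cardiomyocyte library. Camera was also run with background subtracted, where 18 lists passed in this comparison, 6 of them higher. Its result for the Wnt target list is not reported here, so whether background accounts for this rise stays open. Lymphocyte genes rose in 8 of 10 members (8 adjusted over the list alone; camera adjusted p 0.170). Sfrp2 replicate 1 held Cd3e at 87.3, Cd4 at 35.2, Tcf7 at 54.9 and Lef1 at 45.1, against 8.16, 5.02, 4.39 and 21.3 in replicate 2 and 3.68, 7.77, 6.13 and 15.5 in replicate 3. Vwf, Ccnd1, Cd3e, Tcf7 and Lef1 were chosen for naming in this comparison after their values were seen. The Wnt target Axin2 was at 7.91 ± 4.25 against 0 reads, not above background. Kit was at 10.7 ± 3.88 against 10.3 ± 6.71, with a log2 difference of 0.14 (SE 0.481, limma adjusted p = 0.812).

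Over all genes 7426 were higher and 1342 lower by limma, with a median log2 difference of 1.27. Of the higher genes 306 lay above background. Among genes with a mean of at least 10 the split was 464 higher and 1209 lower, and after centring of the median it was 3208 and 4012.

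The comparison of day 12 Sfrp2 with day 12 vehicle asked what the protein changed in c-Kit(+) cells, including whether cardiomyocyte transcripts moved. No gene passed by limma (219 at an unadjusted p under 0.05, where 761 are expected by chance), and DESeq2, edgeR and the authors' deposited p-values gave 0. A weight per library, added after seeing the data, gave 2185, of which 1089 were higher and 1096 lower. In simulation of this comparison 65.2% of genes changed 16-fold and 4.1% of those changed 4-fold were recovered. Only genes with a mean of at least 20 were changed there. Myh6 was at 14.5 ± 1.71 with Sfrp2 and 24.8 ± 12.1 with vehicle (n = 3 each), and Tnnt2 at 32.1 ± 24.1 and 62.3 ± 56.1. Actc1 was at 82.4, 20.1 and 39.3 in the Sfrp2 libraries and at 45.9, 142 and 5.61 in the vehicle libraries. Sfrp2 itself was at 8.80 ± 2.09 and 8.78 ± 9.28, Axin2 at 7.91 ± 4.25 and 2.33 ± 1.40, Gata4 at 5.30 ± 3.38 and 10.5 ± 12.1 and Kit at 10.7 ± 3.88 and 20.6 ± 12.6. The genes with the smallest p, none passing, were Hyal2, Fbxo15, Thbs3, Tbx6, Msh4, Chst1, Slc16a11, Tmem252, Rgs6 and Arhgef16, with means of at most 20.8 in either group.

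The sarcomere score was 4.09 ± 0.397 with Sfrp2 and 4.02 ± 0.696 with vehicle, a log2 difference of 0.063 (exact permutation p = 1, smallest possible 0.1). Leaving out day 12 Sfrp2 replicate 1 gave -0.16 and leaving out day 12 vehicle replicate 3 gave -0.302, while leaving out day 12 vehicle replicate 2 gave 0.39. By camera the macrophage and the erythroid list were lower with Sfrp2 (adjusted p 0.0268 for both, and 0.968 for both with an estimated correlation). Over the macrophage list the mean log2(value + 1) was 3.301, 4.982 and 2.819 in vehicle replicates 1, 2 and 3 and 3.372 to 3.498 with Sfrp2. Only vehicle replicate 2 thus lay above the Sfrp2 libraries, and vehicle replicates 1 and 3 lay below them. The mean log2(value + 1) over the erythroid list was 6.59, 8.65 and 3 in vehicle replicates 1, 2 and 3 and 5.09 to 5.75 with Sfrp2. For the erythroid list the camera adjusted p was 0.896 among genes with a mean of at least 50 (4 members). By the same filter it was 0.00292 for the mitochondrially encoded list (7 members, higher with Sfrp2), against 0.502 for all genes and 0.968 with an estimated correlation. The mean over this list was 11.9, 12.6 and 8.30 in vehicle replicates 1, 2 and 3 and 13.1, 11.5 and 11.7 in Sfrp2 replicates 1, 2 and 3. Vehicle replicates 1 and 2 thus lay within the range of the Sfrp2 libraries. Day 12 vehicle replicate 2 held Lyz2 at 787, against 42.1 to 80.5 in the Sfrp2 libraries.

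Against day 12 vehicle, the day 1 libraries had no gene past the threshold by limma (171 at an unadjusted p under 0.05; DESeq2 called 1, edgeR 0, the authors' deposited p-values gave 3 and a weight per library 2250). In simulation of this comparison 2.3% of genes changed 16-fold were recovered, all of them genes with a mean of at least 20. Spp1 was at 73.8 ± 20.0 (n = 2) and 11.9 ± 9.48 (n = 3), and Ccl2, a monocyte chemokine gene, had 70 and 37 reads at day 1 and 9, 23 and 0 reads with vehicle. Among the other genes with the smallest p were the mitochondrial tRNA genes mt-Ti, mt-Tc, mt-Te and mt-Tq and the Y-linked genes Kdm5d and Eif2s3y, none passing. Kdm5d had 12 and 16 reads at day 1, 0 in each vehicle library, and 0, 9 and 22 in Sfrp2 replicates 1, 2 and 3. The X-linked gene Tsix had 1 read in each day 1 library and 8, 56 and 8 with vehicle. Xist, chosen after its values were seen, was at 17.7 and 13.8 at day 1, 530, 8088 and 39.3 with vehicle, and 5657, 28.9 and 15.9 with Sfrp2. In Xist and Kdm5d, Sfrp2 replicate 1 thus stood apart from replicates 2 and 3, so these libraries do not all come from the same animals. The groups compared here, and day 12 Sfrp2 and vehicle, may differ in the sex of the mice. Sex was not included in any fit.

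Against day 12 Sfrp2, 22 genes were higher at day 1 and 0 lower by limma. Spp1 was higher by 3.45 (SE 0.399, adjusted p = 0.00717), S100a4 by 3.10, Ccl9 by 2.85, Epas1, a hypoxia-responsive transcription factor gene, by 2.41 and C5ar1 by 2.38. The mitochondrial tRNA genes mt-Tc, mt-Te, mt-Ti, mt-Tq and mt-Tm were higher by 2.85, 2.84, 2.71, 2.63 and 2.44. The count was 0 without day 12 Sfrp2 replicate 1 or without day 1 post-MI replicate 2, 6 without day 12 Sfrp2 replicate 3, and 15 without day 1 post-MI replicate 1, 9 of them lower. It was 0 in a fit of all 11 c-Kit libraries, 0 after subtraction of background, 121 by edgeR and 236 by DESeq2. At a threshold of 0.1 it was 149 higher and 228 lower, and with a weight per library 311 higher and 713 lower. With genes of a mean of at least 50 only, the fibroblast and matrix list was lower at day 1 by camera (adjusted p 0.00146, 6 members), against 0.966 over all genes and 0.982 with an estimated correlation.

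The library labelled cardiomyocytes held few sarcomere reads. Myh6 was at 4.43 (2 reads) and Actc1 at 4.43 (2 reads), against 331 ± 106 and 669 ± 60.4 in pre-MI c-Kit(+) cells, while Tnnt2 was at 104 (47 reads). The sarcomere list had a median log2 difference of -2.34 from pre-MI, at percentile 1 of 10000 matched random lists. Against day 1, day 12 vehicle and day 12 Sfrp2 it was -0.94, -0.40 and -0.60, at percentiles 27.4, 51.7 and 27.1. Its largest excesses over the c-Kit(+) libraries were Crhr1 (946 against 2.28 ± 2.35, n = 11), Dos (3069 against 9.38 ± 3.01) and Upf1 (3970 against 14.3 ± 5.99). Fabp4, Cd36, Tmsb4x, Serinc3, B2m, Fos and Sparcl1 were listed at 0. With 1 library there is no replicate check.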

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

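The tests of genes above background, of other scalings, of matched genes and of the cardiomyocyte library were chosen after the results were seen, and the bound of the first, the measure of the second and the matching and interval of the third replaced versions whose values had been seen; the tests by exon length, thinning and other splits were stated first. The patterns below were taken up because they bear on the comparisons. Other results were picked out because 2 groups' differences from pre-MI differed by a direct test. These are 22 genes at day 1 against day 12 Sfrp2, and by camera 2 lists for day 12 Sfrp2 against vehicle, 12 for day 1 against day 12 vehicle and 13 for day 1 against day 12 Sfrp2. With an estimated correlation 0 lists passed in each.

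More genes were higher than lower at day 12 with Sfrp2 than pre-MI, 7426 against 1342. Thinning every library to 97041 reads outside mitochondrial and satellite-like genes left 88.5% of calls higher (median of 10 draws), which argues against depth as the whole cause. The rise per exon kb of the called genes was 2.42 times that of sensory receptor genes, between the bounds stated beforehand, so background reads spread by length may contribute and cannot be told apart from RNA. Of the higher genes 1.33% lay above every sensory receptor gene in all 3 libraries. Draws from 1 distribution give 1.05% in 1 library, and at most that in all 3. The share for all 3 at once was not computed, so this decides nothing either. TMM scaling gave 83.8% higher and edgeR 75.3%, so the excess is not particular to the authors' scaling. Both moved the median log2 difference little, from 1.27 to 1.2 and 1.19, so they cannot exclude an error that all these scalings share. Centring of the median fixes the balance and decides nothing. Among genes with a mean of at least 10 the split turned, with 464 higher and 1209 lower. A change in the cells after MI stays open.

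Sarcomere genes were lower after MI than before. Dilution of RNA by background lowers highly expressed genes most, so each of the 20 members with a pre-MI mean of at least 10 was compared with 50 genes of like pre-MI level. In 8 of 8 libraries after MI the median member lay more than 0.5 log2 below its matched genes, by 0.62 to 1.31, with 13 to 20 of 20 members below. The 95% interval of this gap, from resampled members, lay wholly more than 0.5 below in 4 libraries and below 0 in 7, so dilution stays open, as it does for endothelial genes, 0.23 to 0.53 below theirs. A loss of cardiomyocyte RNA from the sorted cells, or of cells that held it, is a candidate explanation that was not tested.

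The cardiomyocyte library was low in sarcomere RNA against pre-MI c-Kit(+) cells, but against day 12 vehicle the list stood at percentile 51.7 of random lists, and against pre-MI the endothelial, erythroid, respiratory chain and mitochondrially encoded lists were lower still (-4.01, -6.26, -3.40 and -5.79 against -2.34), all at percentile 0. Within each c-Kit(+) group the highest Myh6 value was at most 1.82 times the next, so no c-Kit(+) library stood out by Myh6. Satellite-like genes took 34.6% of the cardiomyocyte library's reads and mitochondrial rRNA 1.08%, which goes with little RNA over genomic background. Day 12 vehicle replicate 3 was alike, with 39.3% and 2.01%. A swap between libraries that both hold little RNA would not show in Myh6, so the Myh6 values cannot exclude it. A wrong label, such a swap or an outside sample stays open, and no biological explanation was tested.

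Other splits of the libraries were counted for 3 comparisons, each with 10 splits, too few for a share under 0.05. For day 12 Sfrp2 against pre-MI the real split called 8768 genes, and the highest other split 1, so 1 of 10 gave as many. For day 12 vehicle against pre-MI, and for Sfrp2 against vehicle, the real split and the highest other called 0, so 10 of 10 gave as many.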

How the results depend on the processing

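Chosen after seeing the data were edgeR, library weights, median centring and background subtraction. The cause of the differences below was not tested. Among genes named under the rule, 1676 alternative values kept direction and side of the threshold, 132 lost the threshold, 145 gained it and 30 changed direction.

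For day 1 against pre-MI (3638 genes) the count was 592 at a mean of at least 10, where fewer genes were tested, 895 with all 11 c-Kit libraries, 10 with the replicate block, 312 by the authors' p-values, 942 by DESeq2, 916 with background subtracted and 1996 to 3580 leaving out 1 library. For day 12 vehicle against pre-MI (0) it was 2364 at pseudocount 0.1, 4245 with all 11 libraries, 1501 with the block, 3916 by the authors' p-values, 1075 by DESeq2, 1907 by edgeR, 820 median-centred, 8282 with weights, 2679 at a threshold of 0.1 and 0 to 6421 leaving out 1 library. For day 12 Sfrp2 against pre-MI (8768) it was 1673 at a mean of at least 10, 5096 by the authors' p-values and 6620 to 8630 leaving out 1 library. For Sfrp2 against vehicle (0) it was 2185 with weights. For day 1 against vehicle (0) it was 2 with the block, 3 by the authors' p-values, 1 by DESeq2, 2250 with weights and 0 to 1 leaving out 1 library. For day 1 against Sfrp2 (22) it was 0 at pseudocount 0.1 and 42 at 8, 40 at a mean of at least 10, 14 with TMM, 0 with all 11 libraries, 89 with the block, 4 by the authors' p-values, 236 by DESeq2, 121 by edgeR, 238 median-centred, 0 with background subtracted, 1024 with weights, 377 at a threshold of 0.1 and 0 to 20 leaving out 1 library. For same-numbered libraries 0 of 15 correlations of their deviations were over 0.1 (-0.474 to 0.096). With so few libraries per group, which also differ in background, this cannot exclude pairing.

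With an estimated correlation 0 lists passed in each comparison. For vehicle against pre-MI 7 passed at a mean of at least 10. For Sfrp2 against vehicle fry gave 0, a mean of at least 10 gave 0 and background subtraction 1. For day 1 against vehicle fry gave 0 and the block 7, and for day 1 against Sfrp2 fry gave 2. Against pre-MI fry gave 11 lists at day 1 (8 higher), 8 with vehicle (7 higher) and 21 with Sfrp2 (13 higher). Camera gave 13, 12 and 14 there. Unlike camera, fry does not set a list against other genes, so the rise over all genes enters its result. The sarcomere score difference of 0.063 became -0.053 at pseudocount 8, -0.062 for members with a mean of at least 10, -0.291 as a median and -0.302 to 0.39 leaving out 1 library. The cardiomyocyte sarcomere median of -2.34 became -1.85 at pseudocount 8.

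The median of all genes moved from 0.70 to 0.85 with TMM and 0.10 with background subtracted (day 1 against pre-MI), from 1.00 to 1.37 by edgeR and 0.17 subtracted (vehicle), and from 1.27 to 0.68 subtracted (Sfrp2). For Sfrp2 against vehicle it moved from 0.22 to 0.02 by edgeR and 0.6 subtracted. For day 1 it moved from -0.14 to 0.08 with TMM and 0.09 subtracted (against vehicle), and from -0.36 to -0.13 with TMM and -0.06 by edgeR (against Sfrp2).

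None of the genes that changed direction passed the threshold in the value reported. Log2 differences for Gata4 were -0.149 median-centred and -0.111 with background subtracted (day 1 against pre-MI), -0.397 median-centred (Sfrp2 against pre-MI), 0.154 with weights and -1.225 to 0.356 leaving out 1 library (Sfrp2 against vehicle), 0.034 with the block and -1.547 to 0.034 leaving out 1 library (day 1 against vehicle), and 0.039 median-centred and -0.914 to 0.032 leaving out 1 library (day 1 against Sfrp2). Kit was at -0.099 median-centred (vehicle against pre-MI), and for Sfrp2 against pre-MI at -0.378 by edgeR, -1.129 median-centred, -0.573 with background subtracted and -0.156 to 0.598 leaving out 1 library. The gene Sfrp2 ranged from -1.01 to 0.551 leaving out 1 library (day 1 against pre-MI), and for Sfrp2 against vehicle was at -0.044 by the authors, -0.49 by DESeq2, -0.323 by edgeR and -0.03 to 1.128 leaving out 1 library. For the same comparison Myh6 was at 0.42 with background subtracted, and Actc1 at -0.471 by the authors, -0.873 by DESeq2, -0.669 by edgeR, -0.226 with weights and -0.985 to 1.232 leaving out 1 library.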

Other observations

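All values in this part come from the fixed lists and no explanation is offered. In day 12 Sfrp2 cells cell cycle genes rose against pre-MI in 22 of 27 members and fell in none (camera adjusted p 0.0168; adjusted p 0.172 with an estimated correlation). Kif11 was at 11.4 ± 1.21 against 0 and Top2a at 25.9 ± 10.6 against 3.34 ± 1.34 (n = 3 each), neither above background. With vehicle the cell cycle list was also higher than pre-MI by camera (median 1.73, adjusted p 0.0262; adjusted p 0.256 with an estimated correlation). There 6 of 27 members passed adjusted over the list alone and none over all genes. With Sfrp2 erythroid genes fell in 6 of 7 members (camera adjusted p 1.01e-05) and immediate early genes in 11 of 19 (1.09e-09), each with an adjusted p of 0.172 with an estimated correlation. Fatty acid oxidation genes fell in 10 of 21 members (1.46e-09; adjusted p 0.172 with an estimated correlation), and mitochondrially encoded genes in 7 of 8 (3.26e-05; adjusted p 0.238 with an estimated correlation). Among genes with a mean of at least 50, which had a median of -1.83, the erythroid, immediate early and mitochondrially encoded lists had medians of -2.49, -1.77 and -2.57 and a camera adjusted p of 0.969 each.

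At day 1 neutrophil genes rose against pre-MI in 6 of 7 members (camera adjusted p 0.00981, and 0.398 with an estimated correlation). Of all 15223 genes 3235 were called higher. The mean log2(value + 1) over the list was 1.729 and 2.766 at day 1, 0 to 0.156 pre-MI and 2.552 in the cardiomyocyte library. The member Mpo was at 3.23 and 6.89 at day 1 and 42.1 in the cardiomyocyte library, and Mmp9 at 0.81, 8.03 and 22.1. Both were at 0 pre-MI. In the progenitor list 1 of 11 genes fell (camera adjusted p 0.00349; adjusted p 0.398 with an estimated correlation; 0.792 by camera among 5 members with a mean of at least 50), and Kit was at 4.54 ± 1.56 (n = 2) against 10.3 ± 6.71 (n = 3), with a limma adjusted p of 0.31.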
